A study of Mus musculus with 26 samples.

How the data were processed

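Left ventricles of BPN/3J and BPH/2J mice given vehicle or Cmpd17b for 28 days were the source of 26 polyadenylated RNA libraries. Per the labels, RNA was extracted with an Aurum kit, libraries were made with the VAHTS Universal V8 kit and sequenced as paired reads on a NovaSeq6000, and the samples belong to batch 1 or batch 2. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7 and aligned with STAR 2.7.9a to the mouse genome build GRCm39 (mm39). The counting program, its use of strand and the gene annotation are not given in the sources used here, so genes that overlap, and near-identical copies, are uncertain. The values used are expected counts per gene, as deposited by the authors, in 1 table of 40413 genes named by symbol. Of these values 93.3% were whole numbers and 2.21% lay more than 0.01 from a whole number. They were rounded to whole counts. All 26 columns matched a sample in the labels, and sample titles give animal identifiers, so each library was taken as a separate mouse. No pair of libraries within a group was identical among 73 pairs.

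Groups were formed by strain and treatment from the labels, with replicates numbered in the order of the samples. Total counts ran from 25476100 to 48648200 per library, written to 6 digits. The mitochondrial share of counts lay between 25.4% and 37.7% in the 25 libraries other than the kidney-like one. Genes were kept by edgeR's filterByExpr on the 4 groups, which left 15558 genes with 26 libraries and 15543 with 25. Counts were scaled by TMM, and CPM in the text are TMM-scaled group means with the SD between mice. The quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, robust fit) was run with 1 coefficient per group and a batch term. All 26 libraries were in 1 fit, so that the groups share the estimate of spread, and the batch effect in BPN_Cmpd17b, which has batch 1 only, is taken from the other groups. P-values were adjusted by Benjamini and Hochberg over all genes tested in a contrast, with a threshold of 0.05. The standard error of a log2 difference is its size divided by the square root of F, and intervals are at 95%. The number of libraries beside a gene is how many of the higher group lie above every library of the lower one. The 6 contrasts were the strain difference under vehicle and under Cmpd17b, the Cmpd17b effect in each strain, their difference and their average.

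Before the data were examined, 41 gene lists (pathways and cell type markers) were fixed, along with the rule for genes named in the text, the contrasts, the tests and most alternatives. The 40 lists with at least 3 members tested entered each contrast. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and also with an estimated correlation and with fry, and adjusted over the lists of a contrast. No call of camera in any contrast held with an estimated correlation. Called members were counted with p adjusted over all genes and with p adjusted over the list alone. The text names part of what the rule selects: the 10 genes per direction with the largest change among those called with an average log2 CPM of at least 1 and a proper symbol, up to 4 members of each list with a called member or a passing camera test, a fixed set of genes of the heart and of blood pressure, and the 10 genes with the smallest p where a contrast called fewer than 10. The same rule was applied to the fit with 25 libraries.

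Alternatives fixed in advance were RLE size factors, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, no filter, a filter of 1 CPM in 7 libraries, no batch term, each batch alone, only the libraries of the groups compared, and leaving out each library of the compared groups in turn. After the data were seen, 2 further sets of libraries were added: the 25 without the library labelled BPH_Cmpd17b replicate 7, with each of these alternatives again, and 23 without that library, BPH_Cmpd17b replicate 6 and BPN_vehicle replicate 7, the 3 libraries with the lowest voom quality weights (0.0142, 0.401 and 0.0997, the next being 0.684). A list of 17 kidney markers was also written after the data were seen. The effect of the drug in BPH/2J was set against the strain difference by the covariance across genes of log2 CPM effects, with 1000 simulations of each gene's noise, without strain or drug differences (for the share of called genes, noise added to the observed strain difference), and with the BPH_vehicle libraries divided in every way into parts of 3 and 4.

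Labels were regrouped at random 80 times per set of libraries, the real grouping included. Fewer than 100 were drawn because of the limit on run time. Strain labels were permuted within each treatment for the strain contrasts, and treatment labels within each strain for the drug contrasts, in both strata of a single fit. On simulated data with 200 genes changed 2-fold, the edgeR fit recovered 55.5% of them for the strain difference under vehicle, 68.5% for Cmpd17b in BPH/2J and 53.5% for Cmpd17b in BPN/3J with 26 libraries. With 25 it recovered 86%, 74.5% and 77%. Of genes changed 1.5-fold it recovered 30.5%, 25% and 16% with 26 libraries and 65.5%, 54.5% and 48.5% with 25. Each share comes from a single simulated set with its own random genes, so differences between contrasts may come from the draw. The simulated genes were independent, with no batch effect and no library set apart, unlike the data. Gene order for the test of neighbouring genes was taken from a table of the assembly GRCm38.p6, used for names and neighbours only, which placed 96.4% of the genes tested. Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.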

Results

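Polyadenylated RNA of the left ventricle was sequenced in 26 libraries, each from a separate mouse of 1 of 2 strains: BPN/3J, which has normal blood pressure, and BPH/2J, which is hypertensive. Mice of either strain had been given vehicle or Cmpd17b, an agonist of formyl peptide receptors, at a daily dose of 50 mg/kg over 28 days. There were 7 libraries from vehicle-treated BPN/3J mice (BPN_vehicle), 5 from BPN/3J mice on Cmpd17b (BPN_Cmpd17b), 7 from vehicle-treated BPH/2J mice (BPH_vehicle) and 7 from BPH/2J mice on Cmpd17b (BPH_Cmpd17b). The labels put 20 libraries in batch 1 and 6 in batch 2. All 5 BPN_Cmpd17b libraries were in batch 1, and each other group had 5 libraries in batch 1 and 2 in batch 2. Total counts per library ran from 25476100 to 48648200. Their mean was 31752900 ± 4906090 (SD, n = 7) in BPN_vehicle, 36584200 ± 4780280 (n = 5) in BPN_Cmpd17b, 35600400 ± 8044770 (n = 7) in BPH_vehicle and 33346400 ± 5210710 (n = 7) in BPH_Cmpd17b. Batch 1 averaged 36126300 and batch 2 averaged 27548600. P-values of single genes below measure spread between mice. Those of camera with the preset correlation of 0.01 treat the genes of a list as nearly independent. They do not measure how far a list's change repeats between mice. In fits of all 26 libraries the spread between mice includes 1 library with a kidney profile, described next.

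One library did not carry a ventricular profile. In the library labelled BPH_Cmpd17b replicate 7, of batch 2, Myh6, the main myosin heavy chain of the adult mouse ventricle, stood at 16.3 CPM (counts scaled to library size), against 13568 to 22901 CPM in the other 25 libraries. Myl2, the ventricular regulatory light chain, stood at 5.04 CPM, against 5175 to 11165 CPM. Kidney transcripts were abundant instead: Kap, a protein of the proximal tubule, reached 24939 CPM, Slc34a1, a phosphate transporter of the same cells, 3336 CPM, and Umod, the uromodulin gene of the thick ascending limb, 2539 CPM. The library's median rank correlation with the other libraries was 0.641, where the other 25 lay between 0.951 and 0.981. Each comparison was therefore computed with all 26 libraries, as planned, and again with the other 25, a choice made after the data were seen. Group means of genes below come from the fit they stand beside.

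**Figure D1:**
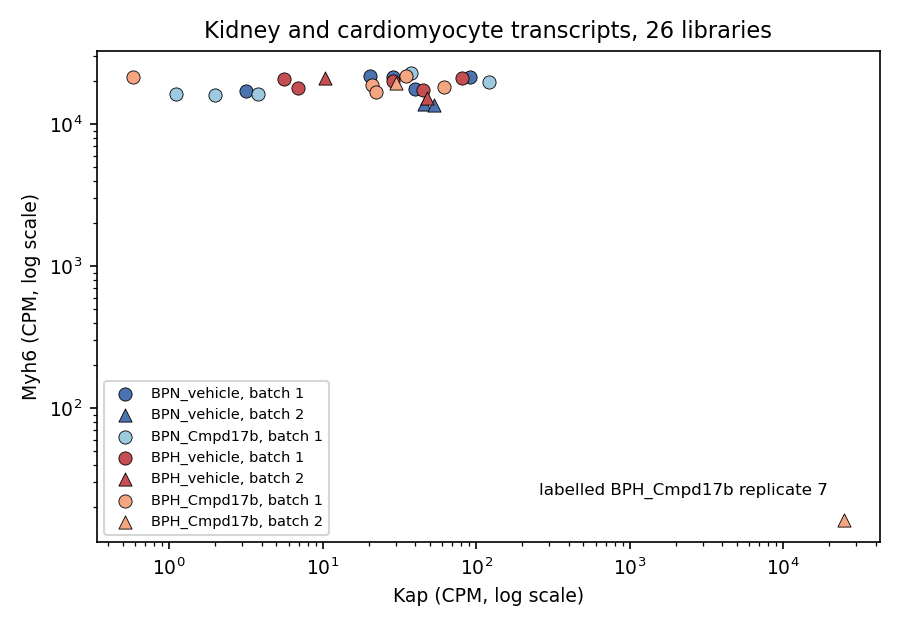
Level of Kap, a kidney transcript, against Myh6, a cardiomyocyte transcript, in each of the 26 libraries (CPM, both axes logarithmic), coloured by group. The library labelled BPH_Cmpd17b replicate 7 lies alone at 24939 CPM of Kap and 16.3 CPM of Myh6.

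The receptors that Cmpd17b acts on were near the detection limit in every group. Fpr1 averaged 0.0985 ± 0.128 CPM (SD, n = 7) in BPN_vehicle, 0.167 ± 0.0589 (n = 5) in BPN_Cmpd17b, 0.0980 ± 0.165 (n = 7) in BPH_vehicle and 0.101 ± 0.123 (n = 7) in BPH_Cmpd17b. Fpr2 averaged 0.153 ± 0.0929, 0.239 ± 0.0858, 0.0986 ± 0.0801 and 0.0976 ± 0.0571 CPM in the same order. Both fell under the filter on low counts, so a difference in either gene was not detectable at this depth.

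The comparison of vehicle-treated BPH/2J with BPN/3J mice asked how the hypertensive ventricle differed from the normotensive one without the drug. The 2 strains were far apart for single genes. Plppr1, a membrane protein related to lipid phosphatases, stood at 20.4 ± 2.91 CPM (SD, n = 7) in BPH/2J and 0.0338 ± 0.0422 CPM (n = 7) in BPN/3J, a log2 difference of 9.15 ± 0.41 (SE, adjusted p = 3.8e-14). Gdpd3, a lysophospholipid-cleaving phosphodiesterase, stood at 26.5 ± 3.30 against 0.315 ± 0.167 CPM (6.38 ± 0.24, adjusted p = 1.3e-15). Edn3, which encodes endothelin-3, stood at 7.84 ± 0.636 against 0.121 ± 0.105 CPM (6.02 ± 0.41, adjusted p = 7.2e-11). Sycp2, a protein of the synaptonemal complex, was lower in BPH/2J by a log2 difference of -5.37 ± 0.26 (adjusted p = 8.4e-14), and so was Rab6b, a small GTPase of vesicle transport (-4.51 ± 0.51, adjusted p = 6.3e-07). For each of these 5 genes all 7 libraries of the higher strain lay above all 7 of the other. By edgeR, 743 genes were higher and 749 lower in BPH/2J at an adjusted p under 0.05, or 9.59% of the 15558 tested. Of the 1492, 745 differed by more than 2-fold. With 25 libraries 1423 were higher and 1513 lower, or 18.9% of the genes tested. Among them were 1486 of the 1492 genes, each in the same direction. Batch 1 alone gave 2402 genes and batch 2 alone, with 2 libraries in each strain, gave 1168. Among the largest differences were members of families of near-identical copies, whose reads cannot be assigned to 1 copy with certainty: Rps15a-ps6 (-5.62 ± 0.24), Tma7-ps (6.26 ± 0.28), Rpl26 (4.83 ± 0.17), Serpina3h (-5.68 ± 0.52) and Slc28a2b (7.25 ± 0.74).

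Some complement and antigen presentation genes were lower in BPH/2J. Of 34 members, 11 fell and 0 rose (14 and 1 when adjusted over the list alone), with a median log2 difference of -0.56. Camera, a test of the list against all other genes, gave an adjusted p of 0.000242 with a preset correlation and adjusted p = 0.99 with an estimated correlation, and fry, which asks whether the list moves on balance, gave 0.0468. C7, a component of the membrane attack complex, stood at 4.99 ± 1.48 CPM in BPH/2J and 17.01 ± 6.61 CPM in BPN/3J (-1.73 ± 0.22, adjusted p = 4.6e-06). The class I histocompatibility gene H2-K1 stood at 73.0 ± 13.0 and 144 ± 51.4 CPM (-0.96 ± 0.19, adjusted p = 0.00117), and H2-Q6 differed by -1.38 ± 0.24 (adjusted p = 0.000241). For these 3 genes all 7 BPN/3J libraries lay above all 7 BPH/2J libraries. BPN_vehicle replicate 7 was high in several genes of class I presentation, with H2-K1 at 248 CPM. Without it the median of the list was -0.38 (camera adjusted p = 0.00344), and H2-K1 was still called (-0.79, adjusted p = 0.00257). Class I genes are highly similar to each other and differ between strains, so counts of a single copy are uncertain. In the interferon response list 3 of 39 members were lower and 0 higher, also when adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.133). That is no larger a share than the 9.59% called among all genes tested. Xaf1, an interferon-induced regulator of apoptosis, differed by -1.95 ± 0.19 (adjusted p = 6.3e-08, 7 of 7 libraries), and Tap1, a peptide transporter for class I loading, by -0.86 ± 0.23 (adjusted p = 0.0146, 6 of 7 libraries). In batch 2 alone Tap1 was not called (-0.38, adjusted p = 0.414). Of 12 tested T lymphocyte and NK cell markers, 3 were higher and 1 lower in BPH/2J (4 and 1 when adjusted over the list alone), and fry gave 0.0468. Gzma, a granule protease of cytotoxic cells, stood at 1.06 ± 0.309 against 0.136 ± 0.120 CPM (2.96 ± 0.45, adjusted p = 3.9e-05, 7 of 7 libraries), Ncr1, a receptor of NK cells, was higher by 3.33 ± 0.68 (adjusted p = 0.00134, 6 of 7), and Cd4 was lower (-1.26 ± 0.31, adjusted p = 0.00841, 5 of 7). In batch 2 alone the calls of Gzma (2.10, adjusted p = 0.0993) and Cd4 (-1.08, adjusted p = 0.305) ended.

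Some matrix, ion channel and growth factor genes differed. With 26 libraries the matrix and ion channel lists held no larger a share of calls than the 9.59% of all genes tested. In the extracellular matrix and fibrosis list 4 of 60 members were higher in BPH/2J and 0 lower (4 and 0 when adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.133). They were the metalloproteinases Mmp3 (4.85 ± 0.63, adjusted p = 4.5e-06) and Mmp9 (1.35 ± 0.35, adjusted p = 0.0126), the microfibril protein Mfap4 (2.51 ± 0.67, adjusted p = 0.0157) and the type VI collagen chain Col6a3, at 23.9 ± 5.22 against 11.01 ± 2.74 CPM (1.12 ± 0.28, adjusted p = 0.0103), each higher in 7 of 7 libraries. In batch 2 alone the call of Mmp9 ended (2.20, adjusted p = 0.0873). Of 35 cardiac ion channel genes 3 were higher and 0 lower (3 and 0 when adjusted over the list alone). Among them Kcne1, a subunit of the slow delayed rectifier, differed by 0.91 ± 0.17 (adjusted p = 0.000629), in 7 of 7 libraries. With 25 libraries 12 of the 35 were higher and 2 lower, where 18.9% of all genes tested were called. Of the formyl peptide receptor and resolution mediator list, 14 of 24 genes could be tested. Lgr6, a receptor for the lipid mediator maresin-1, stood at 58.3 ± 6.78 CPM in BPH/2J and 5.74 ± 0.843 CPM in BPN/3J (3.33 ± 0.51, adjusted p = 4.5e-05), and Mertk, a receptor for apoptotic cells, was lower (3.19 ± 0.552 against 9.09 ± 3.46 CPM, -1.59 ± 0.37, adjusted p = 0.00544), both in 7 of 7 libraries. They made up the list's calls, 1 higher and 1 lower, also when adjusted over the list alone. Angpt1 was higher (1.23 ± 0.27, adjusted p = 0.00306) and Angpt2 lower (-1.06 ± 0.20, adjusted p = 0.000519) in 7 of 7 libraries, though Angpt2 was not called in batch 2 alone (-0.63, adjusted p = 0.26). These growth factors act on the same endothelial receptor.

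Genes of wall stress, hormone control and glucose use changed in part. With 26 libraries the renin-angiotensin-aldosterone and glucose lists held no larger a share of calls than the 9.59% of all genes tested. Of 24 cardiac stress and fetal genes 4 were higher and 1 lower in BPH/2J (4 and 1 when adjusted over the list alone), among them the beta-tropomyosin gene Tpm2 (1.34 ± 0.29, adjusted p = 0.0028, 5 of 7 libraries) and, lower, the muscle growth inhibitor Mstn (-2.39 ± 0.53, adjusted p = 0.00326, 7 of 7). The B-type natriuretic peptide gene Nppb had a mean of 178 ± 30.8 CPM in BPH/2J and 364 ± 137 CPM in BPN/3J, all 7 libraries against all 7. It was not called in the edgeR fit of all 26 libraries (-1.03 ± 0.57, adjusted p = 0.337) and was called by edgeR with 25 (-1.03 ± 0.18, adjusted p = 9.1e-05) and in batch 1 alone (-1.04, adjusted p = 0.000482). Neither the atrial natriuretic peptide gene Nppa (0.31 ± 0.65, adjusted p = 0.887) nor the slow myosin Myh7 (-0.33 ± 0.56, adjusted p = 0.846) was called with 26 libraries by edgeR. Nppa was called in batch 2 alone (1.04, adjusted p = 0.0225) and by limma voom (0.78, adjusted p = 0.0382). Of the 2 BPH_vehicle libraries in batch 2, replicate 7 also held Myl7, an atrial light chain, at 72.8 CPM. For Nppa, 1 of 7 BPH_vehicle libraries lay above all BPN_vehicle libraries. With 25 libraries Myh7 was called by DESeq2 (-0.35, adjusted p = 0.0433), and by edgeR without BPH_vehicle replicate 2 or BPN_vehicle replicate 2 (-0.42 in both, adjusted p = 0.0371 and 0.0329). Agt, which encodes angiotensinogen, was lower in BPH/2J, 0.721 ± 0.127 against 4.57 ± 0.856 CPM (-2.67 ± 0.61, adjusted p = 0.00443, 7 of 7 libraries). It was the 1 gene called by edgeR with 26 libraries of 14 tested in the renin-angiotensin-aldosterone list, also when adjusted over the list alone. The angiotensin receptor gene Agtr1a was called higher by limma voom (0.22, adjusted p = 0.0304). EdgeR called Agtr1a with 25 libraries, a call that ended, among others, with RLE size factors (0.34, adjusted p = 0.0539). Ren1 lay under the filter. Of 40 glycolysis and glucose genes 1 was higher and 2 lower, also when adjusted over the list alone. Phkg1, a catalytic subunit of phosphorylase kinase, stood at 3.64 ± 0.697 against 21.9 ± 4.90 CPM (-2.57 ± 0.22, adjusted p = 6.5e-09, 7 of 7 libraries), the phosphofructokinase Pfkp differed by -0.64 ± 0.15 (adjusted p = 0.00407, 7 of 7), and the hexokinase Hk1 by 0.55 ± 0.13 (adjusted p = 0.00686, 6 of 7). Pfkp was not called in batch 2 alone (-0.36, adjusted p = 0.177), nor Hk1 without the batch term (0.53, adjusted p = 0.08). Some hepatocyte transcripts were also called lower in BPH/2J: Alb (-5.03 ± 1.43, adjusted p = 0.024), Apoa1 (-4.51 ± 1.29, adjusted p = 0.0241) and Serpina3k (-5.80 ± 1.43, adjusted p = 0.00798), with 4 of 7 BPN/3J libraries above all of BPH/2J. Alb reached 212, 337 and 35.3 CPM in BPN_vehicle replicates 1, 2 and 4, and all 3 calls ended without replicate 4 (adjusted p = 0.201, 0.184 and 0.145). Those of Alb and Apoa1 also ended without BPH_vehicle replicate 1 (adjusted p = 0.053 and 0.064), 6 (0.0502 and 0.0504) or 7 (0.06 and 0.0582), and that of Apoa1 without replicate 5 (0.05004). With no filter on low counts Alb (adjusted p = 0.0553) and Apoa1 (adjusted p = 0.0547) were not called, nor was Alb in batch 1 alone (-3.42, adjusted p = 0.131) or when the fit held only these 2 groups (-5.12, adjusted p = 0.0661).

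**Figure D2:**
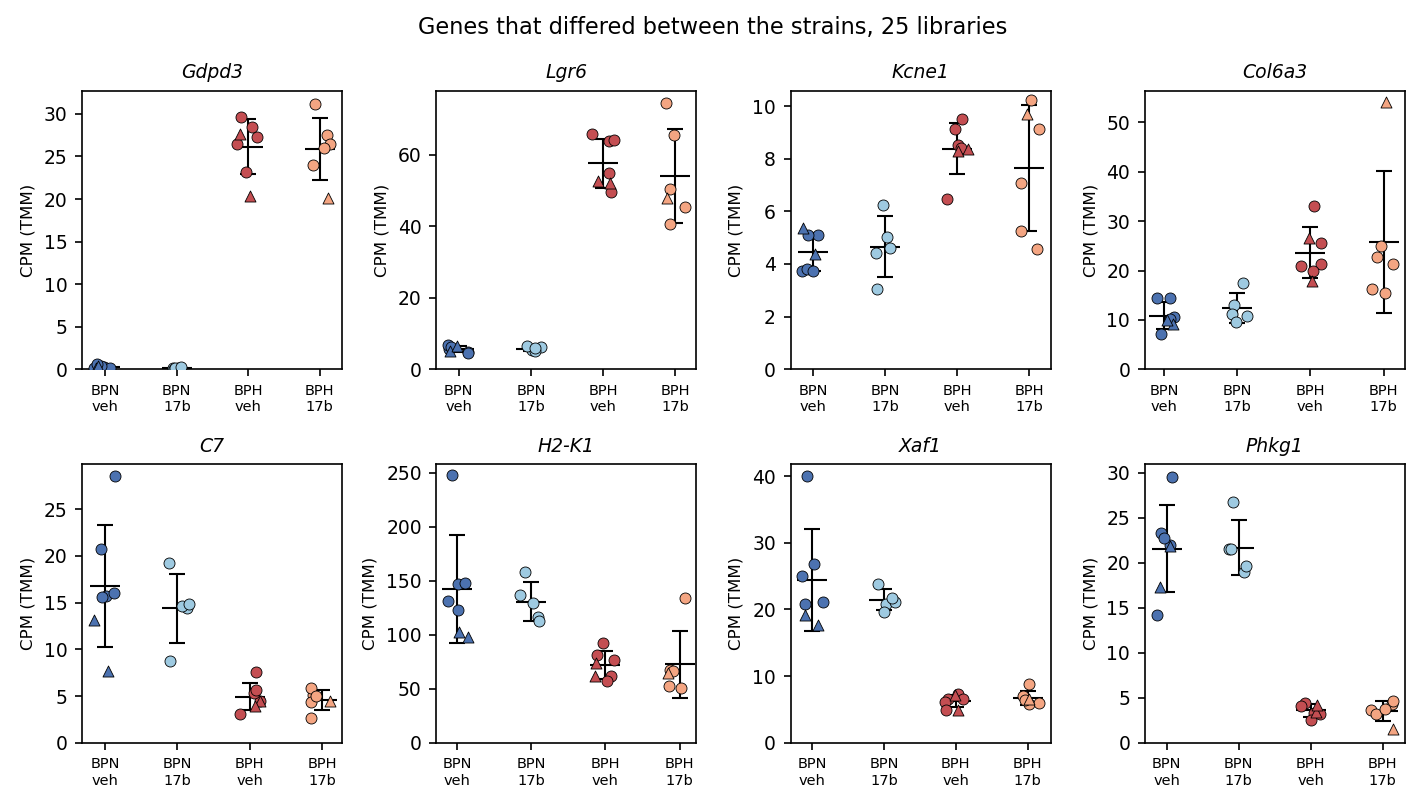
Normalised level (CPM) of 8 genes that differed between the strains in the 25 libraries other than the kidney-like one, by group. Points are mice, triangles are batch 2, and bars show mean and SD; BPH/2J libraries lie above BPN/3J for Gdpd3 and Lgr6 and below it for Phkg1 and Xaf1.

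The same strain comparison in Cmpd17b-treated mice asked whether the strains still differed on the drug. They did, through many of the same genes. Plppr1 (8.62 ± 0.46, adjusted p = 1.1e-12), Gdpd3 (7.39 ± 0.30, adjusted p = 1.1e-14) and Edn3 (6.86 ± 0.50, adjusted p = 3.5e-10) were higher in 7 of 7 BPH_Cmpd17b libraries than in any BPN_Cmpd17b library. Without the kidney-like library this held in 6 of 6. The retinoid transporter gene Abca4 (-4.02 ± 0.29, adjusted p = 3.2e-10), the cytokine gene Il15 (-3.96 ± 0.28, adjusted p = 3.0e-10), the xenobiotic oxidase Cyp2b10 (-4.83 ± 0.61, adjusted p = 3.9e-06) and C7 (-1.60 ± 0.25, adjusted p = 6.1e-05) were lower in BPH/2J, with 5 of 5 BPN/3J libraries above all others. Mfap4 was higher (3.25 ± 0.83, adjusted p = 0.0135, 6 of 7 libraries), and was not called when the fit held only these 2 groups (2.78, adjusted p = 0.176). H2-K1 was lower (-0.80 ± 0.21, adjusted p = 0.0184, 2 of 5 libraries), a call that ended without BPN_Cmpd17b replicate 4 (-0.73, adjusted p = 0.0619) and when the fit held only these 2 groups (-0.82, adjusted p = 0.0986). By edgeR Nppa was not called with all 26 libraries (1.98 ± 0.79, adjusted p = 0.156) and was higher in BPH/2J without the library labelled BPH_Cmpd17b replicate 7 (906 ± 808 against 171 ± 53.2 CPM, 2.12 ± 0.47, adjusted p = 0.00263, 6 of 6 libraries). Agt was called lower by edgeR without it (-2.09 ± 0.20, adjusted p = 4.5e-09), but not with it (-1.0 ± 0.73, adjusted p = 0.505). Limma voom called Agt lower with all 26 libraries (-1.945, adjusted p = 8.7e-09).

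In this comparison 645 genes were higher and 550 lower in BPH/2J by edgeR, or 7.68% of the genes tested. Of the 1195, 913 were also called under vehicle, all in the same direction, where 57.3 would be shared by independent calls. Without the library labelled BPH_Cmpd17b replicate 7 there were 1163 higher and 1034 lower genes, or 14.1% of the genes tested. Batch 1 alone, the only batch with BPN_Cmpd17b libraries, gave 1961. The fatty acid oxidation and lipid handling list had 6 of 42 members lower and 0 higher (8 and 0 when adjusted over the list alone), with a median of -0.33. Its camera adjusted p was 0.000118, and adjusted p = 0.929 with an estimated correlation. In the complement and antigen presentation list 5 of 34 members were lower and 0 higher (8 and 0 when adjusted over the list alone), with a median of -0.24 and a camera adjusted p of 0.000687, and adjusted p = 0.929 with an estimated correlation. These values are from 26 libraries. With 25 the medians were -0.22 for fatty acid oxidation (camera adjusted p = 0.00092) and -0.29 for complement (camera adjusted p = 0.0286). The complement call with 25 ended in 5 of 11 fits that left out 1 library. With 25 libraries 12 of 60 extracellular matrix genes were higher and 0 lower (16 and 0 when adjusted over the list alone), with a median of 0.53 and a camera adjusted p of 0.00278. That list had adjusted p = 0.981 with an estimated correlation, and without BPH_Cmpd17b replicate 6 its median was 0.28 (camera adjusted p = 0.0276).

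The comparison of Cmpd17b with vehicle in BPH/2J mice asked what the drug changed in the hypertensive ventricle. No gene passed the test, so the following are values, not calls. Fstl3, a secreted inhibitor of activins, had the smallest p with 26 libraries (log2 difference 0.67 ± 0.16, adjusted p = 0.659, 5 of 7 Cmpd17b libraries above all vehicle libraries). Slc25a23, a mitochondrial ATP-magnesium carrier, had 0.37 ± 0.09 (adjusted p = 0.659, 7 of 7). Both counts include the kidney-like library. Without it they were 4 of 6 for Fstl3 and 6 of 6 for Slc25a23. With 25 libraries Klf10, a TGF-beta-induced transcription factor, averaged 17.5 ± 2.40 CPM (SD, n = 6) on Cmpd17b and 12.2 ± 1.43 CPM (n = 7) on vehicle (0.52 ± 0.13, adjusted p = 1, 6 of 6). With 26 libraries the collagen genes Col1a1 (0.36 ± 0.47, adjusted p = 0.823) and Col3a1 (0.09 ± 0.48, adjusted p = 0.962), and Nppa (0.45 ± 0.65, adjusted p = 0.843), Nppb (0.02 ± 0.56, adjusted p = 0.991) and Myh7 (-0.28 ± 0.56, adjusted p = 0.881), differed by less than their SE. That SE includes the distance of the kidney-like library from the ventricles, so it is not the spread between ventricles alone. BPH_Cmpd17b replicate 6 stood far above the rest of its group, at 305 CPM of Col1a1, 746 CPM of Col3a1, 2545 CPM of Nppa and 37.7 CPM of the collagen cross-linker Lox. When it was left out of the 26, 6 positive values of named genes turned negative: Col1a1 (-0.54, adjusted p = 0.488), Col3a1 (-0.76, adjusted p = 0.401), Nppa (-0.36, adjusted p = 0.805), Nppb (-0.37, adjusted p = 0.774), Lox (from 0.81 to -0.25, adjusted p = 0.689) and the skeletal alpha-actin gene Acta1 (from 0.43 to -0.11, adjusted p = 0.933). Agtr1a, an angiotensin receptor gene, turned from -0.06 to 0.0218. Col3a1 was also negative in batch 1 alone (-0.40) and with limma voom (-0.17), and Col1a1 in batch 1 alone (-0.12). Col3a1 also changed sign without BPH_vehicle replicate 7 (-0.06), and Nppb, near 0, in batch 2 alone (-0.0267) and without BPH_Cmpd17b replicate 3 or BPH_vehicle replicate 1, 3 or 5 (-0.0243 to -0.00639). By edgeR 0 genes were called with either set of libraries, with 970 at an unadjusted p under 0.05 in 26 libraries and 287 in 25. DESeq2 (1451 and 324) and limma voom (662 and 604) also called 0. Batch 1 alone gave 0 calls and 239 genes at an unadjusted p under 0.05. Batch 2 alone gave 0 and 89, and without the library labelled BPH_Cmpd17b replicate 7 it set replicate 6 by itself against 2 vehicle libraries and gave 249 calls, 222 of them higher.

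In this comparison several fixed lists passed camera with the preset correlation, none did with an estimated correlation, and some calls ended or turned without single libraries. The extracellular matrix and fibrosis list had a median log2 difference of 0.07 with 26 libraries (camera adjusted p = 0.204, direction down, against the median's sign) and of 0.21 with 25, where 52 of 60 members were positive (adjusted p = 1.5e-04, and adjusted p = 0.857 with an estimated correlation). Leaving out BPH_Cmpd17b replicate 6 from the 25 turned it to -0.16 (adjusted p = 2.3e-08), and batch 1 alone gave -0.12 (adjusted p = 2.4e-05, and adjusted p = 0.837 with an estimated correlation). The 76 nuclear-encoded respiratory chain genes had a median of -0.28 with 26 libraries, 0 of them positive (camera adjusted p = 9.2e-25), and of -0.12 with 25, 2 of them positive (adjusted p = 3.9e-19). These had adjusted p = 0.521 and adjusted p = 0.625 with an estimated correlation, and batch 1 alone gave -0.07 (adjusted p = 4.6e-05). Of the 25, leaving out BPH_Cmpd17b replicate 6 gave -0.06 (adjusted p = 0.00276) and leaving out BPH_vehicle replicate 7 gave -0.08, both still called. The 42 fatty acid oxidation genes had a median of -0.25 (camera adjusted p = 4.8e-09) with 26 and of -0.08 (adjusted p = 1.3e-07) with 25 libraries, and adjusted p = 0.521 and adjusted p = 0.625 with an estimated correlation. This call ended when BPH_Cmpd17b replicate 6 was left out of the 25 (-0.0102, adjusted p = 0.128). With 26 libraries the sarcomere list had a median of -0.24 (camera adjusted p = 1.0e-07, and adjusted p = 0.521 with an estimated correlation), and without the library labelled BPH_Cmpd17b replicate 7 its median was 0.03 (adjusted p = 0.663). With 25 libraries 29 of 39 inflammatory genes (median 0.11, adjusted p = 0.000687, and adjusted p = 0.698 with an estimated correlation) and 7 of 7 erythroid genes (0.27, adjusted p = 0.000543, and adjusted p = 0.625 with an estimated correlation) were positive. The inflammatory call ended without BPH_Cmpd17b replicate 4 (0.08, adjusted p = 0.0559) or 6 (0.0131, adjusted p = 0.354), and its median was 0.07 without BPH_vehicle replicate 4 or 5. The erythroid median was 0.18 without BPH_vehicle replicate 6 (adjusted p = 0.0312). The 30 proliferation genes had 0.29 with 25 libraries, 25 of them positive (adjusted p = 0.000164, and adjusted p = 0.723 with an estimated correlation), a call that ended without BPH_Cmpd17b replicate 6 (0.0175, adjusted p = 0.621) or BPH_vehicle replicate 7 (0.16, adjusted p = 0.116). The largest medians came from lists with 5 tested markers. Adipocyte markers had -0.79 with 26 libraries (adjusted p = 0.0796) and -0.69 with 25, 0 of 5 positive (adjusted p = 0.0198, and adjusted p = 0.6 with an estimated correlation), a call that ended without BPH_Cmpd17b replicate 5 or 6 or BPH_vehicle replicate 4, 6 or 7 (-0.64 to -0.35). Skeletal muscle markers had -0.60 with 26 (adjusted p = 0.00354) and -0.37 with 25 (adjusted p = 0.0079), 0 of 5 positive in both. They had adjusted p = 0.521 and adjusted p = 0.6 with an estimated correlation, and the call with 25 ended without BPH_Cmpd17b replicate 4 (-0.28, adjusted p = 0.0626) or BPH_vehicle replicate 4 (-0.15, adjusted p = 0.14), that with 26 in batch 1 alone (-0.20, adjusted p = 0.538). None of these lists had a called member, and 0 members were called when adjusted over the list alone.

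**Figure D3:**
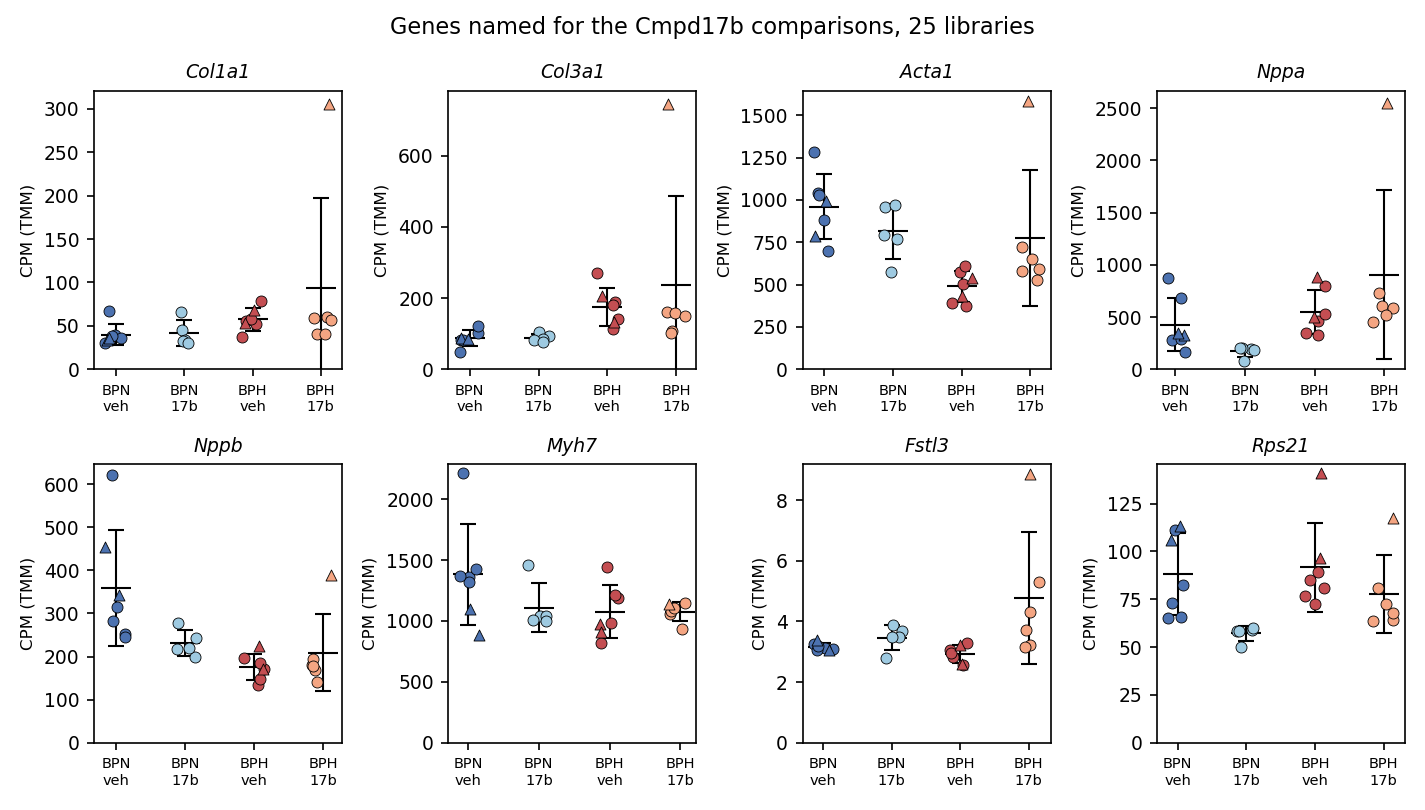
Normalised level (CPM) of 8 genes in the 25 libraries other than the kidney-like one, by group, with triangles for batch 2 and bars for mean and SD. By edgeR none of the 8 was called between Cmpd17b and vehicle, and BPH_Cmpd17b replicate 6 stands apart at 305 CPM of Col1a1 and 2545 CPM of Nppa.

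The comparison of Cmpd17b with vehicle in BPN/3J mice asked what the drug did without hypertension. Here too no gene passed the test by edgeR. Rps21, a protein of the small ribosomal subunit, averaged 57.1 ± 3.91 CPM (SD, n = 5) on Cmpd17b and 88.1 ± 21.4 CPM (n = 7) on vehicle (with 26 libraries -0.46 ± 0.12, adjusted p = 0.979, 7 of 7 vehicle libraries above all Cmpd17b libraries). Pih1d1, a subunit of a chaperone complex, had -0.35 ± 0.09 (adjusted p = 0.979, 7 of 7). Group means and counts of libraries here are not adjusted for batch, and 2 of the 7 vehicle libraries were in batch 2. With 26 libraries the batch effect applied to this comparison rests in part on the kidney-like library. With 25 libraries Nppa averaged 171 ± 53.2 CPM on Cmpd17b and 425 ± 254 CPM on vehicle (-1.18 ± 0.43, adjusted p = 0.514, 6 of 7), and Gamt, an enzyme of creatine synthesis, had -0.79 ± 0.20 (adjusted p = 0.514, 5 of 7). By edgeR 0 genes were called with 26 libraries and with 25, with 683 and 1506 at an unadjusted p under 0.05. Limma voom also called 0 (941 and 943), and DESeq2 called 0 of 26 and 1 of 25 (780 and 1612). That gene was Nrgn, a calmodulin-binding protein, at 0.953 ± 0.375 CPM (n = 5) on Cmpd17b and 3.33 ± 2.84 CPM (n = 7) on vehicle (DESeq2 -1.83, adjusted p = 0.0285; edgeR -1.84 ± 0.40, adjusted p = 0.514), and it is named after its values were seen. Batch 1 alone, which holds all BPN_Cmpd17b libraries, gave 0 calls and 1945 genes at an unadjusted p under 0.05.

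Among the lists in BPN/3J, with 25 libraries, the respiratory chain list had a median of -0.13, 13 of 76 members positive (camera adjusted p = 2.6e-05, and adjusted p = 0.749 with an estimated correlation), and of -0.08 without BPN_Cmpd17b replicate 1 (adjusted p = 0.0229) or BPN_vehicle replicate 7 (adjusted p = 1.8e-05). The fatty acid oxidation list had 0.10, with 33 of 42 positive (adjusted p = 0.0137, and adjusted p = 0.749 with an estimated correlation), a call that ended without BPN_vehicle replicate 7 (0.0200, adjusted p = 0.386) or BPN_Cmpd17b replicate 5 (0.07, adjusted p = 0.0801). The 12 endothelial markers had -0.29, 0 of them positive (adjusted p = 0.00115, and adjusted p = 0.749 with an estimated correlation). Among them Fabp4 had -0.48 ± 0.19 and Emcn -0.34 ± 0.15. Without BPN_vehicle replicate 7, in which Fabp4 reached 1390 CPM and Emcn 81.2 CPM, the endothelial median was -0.05 (adjusted p = 0.265), and the call also ended without the batch term (-0.20, adjusted p = 0.0639). The interferon response list had -0.21 (camera adjusted p = 0.0207, and adjusted p = 0.749 with an estimated correlation), a call that ended without BPN_Cmpd17b replicate 2 (adjusted p = 0.0735) or 3 (0.0913) and without BPN_vehicle replicate 7 (0.855), where its median was 0.00495. No member of these lists was called, also when adjusted over the list alone.

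The interaction asked whether the drug effect differed between the strains, and the average over strains asked for a shared effect. No gene passed either test. With 25 libraries the interaction was 1.83 ± 0.58 for Nppa (adjusted p = 0.917), 0.90 ± 0.28 for Ankrd1, a stretch-induced sarcomere gene (adjusted p = 0.917), and 0.77 ± 0.22 for Col18a1, a basement membrane collagen (adjusted p = 0.917). BPH_Cmpd17b replicate 6 stood apart from its group in Nppa (2545 against at most 726 CPM) and in Ankrd1 (3016 against at most 1687 CPM). Averaged over strains with 26 libraries, Rps21 had -0.33 ± 0.08 (adjusted p = 0.558), Fstl3 0.44 ± 0.11 (adjusted p = 0.558) and Fcgr2b, an inhibitory antibody receptor, 0.59 ± 0.17 (adjusted p = 0.558). The interaction gave 0 calls by edgeR, with 341 genes at an unadjusted p under 0.05 in 26 libraries and 595 in 25. The average gave 0 calls, with 1319 and 1017. DESeq2 (443 and 670, and 1583 and 1091) and limma voom (723 and 736, and 994 and 902) also called 0 for both. Averaged over strains with 25 libraries the respiratory chain list had a median of -0.13 (camera adjusted p = 3.3e-16, and adjusted p = 0.605 with an estimated correlation; -0.08 without BPH_Cmpd17b replicate 6, adjusted p = 9.6e-05). The 13 mitochondrially encoded mRNAs had the opposite sign, with a median of 0.08 and 9 positive (adjusted p = 0.0327, and adjusted p = 0.605 with an estimated correlation), a call that ended without BPH_Cmpd17b replicate 5, BPH_vehicle replicate 3, BPN_Cmpd17b replicate 5 or BPN_vehicle replicate 3 or 4 (adjusted p up to 0.0918). Of the macrophage markers 16 of 16 were positive with a median of 0.14 (adjusted p = 0.00306, and adjusted p = 0.605 with an estimated correlation). The macrophage call ended without BPH_Cmpd17b replicate 6 (0.04, adjusted p = 0.116). At the median gene the 95% interval of the drug effect reached a factor of 1.30 either way in BPH/2J and 1.34 in BPN/3J with 26 libraries, and 1.20 and 1.21 with 25.

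**Figure D4:**
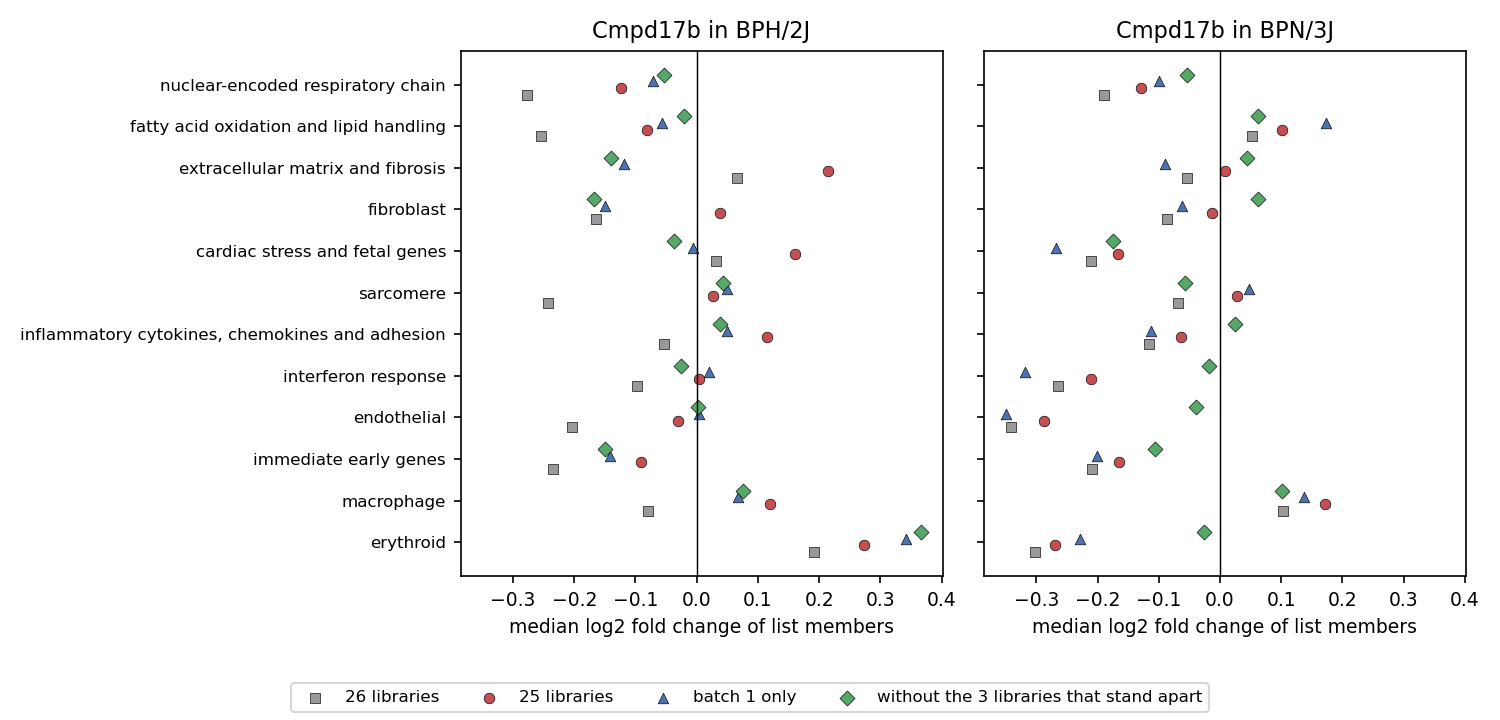
Median log2 difference between Cmpd17b and vehicle of 12 gene lists in BPH/2J and in BPN/3J, with 26 libraries, 25 libraries, batch 1 only and without the 3 libraries that stand apart. The respiratory chain list is below 0 in all of them, from -0.28 to -0.05, and the extracellular matrix list in BPH/2J lies between -0.14 and 0.21.

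A last comparison asked whether Cmpd17b in BPH/2J moved genes back towards BPN/3J. Both effects use the same vehicle-treated BPH/2J mice, which alone makes them run against each other across genes. Over 15558 genes the correlation of the 2 effects was -0.15, and genes are not independent replicates. Their covariance was -0.0369 with 26 libraries. In 1000 simulations of noise alone, with neither a strain difference nor a drug effect, the median covariance was -0.0498, with a 95% range of -0.0538 to -0.0458 that leaves out the spread that strain differences and correlated genes add. With 25 libraries it was -0.00949, against -0.0233 (-0.0256 to -0.0212). Opposite signs were found for 52.8% and 52.4% of genes. Of the 1492 genes called between the strains, 848 (56.8%) moved back towards BPN/3J on the drug, and of the 2936 called with 25 libraries 1589 (54.1%) did, where simulation that kept each gene's strain difference gave 50.1% and 50.0%, with ranges of 47.5 to 52.8% and 48.2 to 51.9%. Picking the genes with the same BPH_vehicle mice raises this share and is not in the simulation. When the BPH_vehicle mice were divided so that each effect had its own controls, in 35 divisions with 2 values each, the median covariance was -0.0174 with 26 libraries, 15 of 70 values positive, and 0.0104 with 25, 70 of 70 positive. In these divisions as many genes, picked by 1 part of the controls and set against the other part, moved back in a median of 50.9% and 45.5%. With 25 libraries no opposition of the drug effect to the strain difference beyond that of the shared controls was found. With 26 libraries a negative median was left after the controls were divided, but that fit counts the kidney-like library as a treated ventricle. The simulated noise with 26 libraries also includes that library, so this set cannot decide the question.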

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

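Of the tests in this part, those for kidney tissue, for a mixture with ventricle RNA, for the source of low kidney transcripts and of Cubn, for gene copies and for strain variants were chosen only after the result was seen, as was the set of 25 libraries, while those for a BPN/3J animal, for inherited segments and the regroupings of samples were fixed before their results were seen.

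The library labelled BPH_Cmpd17b replicate 7 stood far from its group in rank correlation with other libraries (0.641, gap over range 0.959) and in the sum of 17 kidney markers (39164 CPM against at most 93.7 CPM in the rest of the group, gap over range 0.998). The tables argue against ventricle RNA at 5% or more of this library, since the median of 12 cardiomyocyte markers was 0.000808 of that in the other BPH_Cmpd17b libraries. They also argue against a BPN/3J animal, since 11.1% of 18 BPN/3J-specific genes were found in it, against 83.3% of 24 BPH/2J-specific genes. Kidney tissue in place of ventricle, for which that ratio of 0.000808 is needed, is a candidate explanation. Which animal or tube it came from was not tested, and no biological explanation was tested.

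Kidney transcripts were also present at low levels in the other 25 libraries: Kap, the most abundant, ran from 0.580 to 122 CPM, with a median of 28.8 CPM, and was above 1 CPM in 24 of them. By group its median was 39.7 CPM in BPN_vehicle, 3.78 in BPN_Cmpd17b, 28.8 in BPH_vehicle and 26.3 in BPH_Cmpd17b. The ranges overlapped widely, at 3.17 to 90.9, 1.11 to 122, 5.61 to 80.3 and 0.580 to 62.0 CPM in the same order. By batch, Kap ran from 0.580 to 122 CPM in batch 1. In batch 2, which holds the kidney-like library, it ran from 10.3 to 52.7 CPM in the others. Of 219 pairs of a marker and a library, 182 (83.1%) kept their ratio to Kap within 3-fold of that in the kidney-like library, over 14 genes and 22 libraries, and 176 of 206 (85.4%) did without Cubn, the cubilin gene, which argues against expression of these other markers by the ventricle itself. Cubn lay above that ratio in all 12 BPN/3J libraries, by 3.14-fold to 161-fold with a median of 9.62-fold, at 1.80 to 4.46 CPM whether Kap was high or low. That argues against this kidney source for the Cubn counts of BPN/3J, and expression of Cubn in the BPN/3J ventricle stays open. Pairs of the other markers outside the 3-fold bound all lay under the ratio of the kidney-like library. Most were for Aqp2, Umod, Slc12a3, Slc12a1 or Calb1. Aqp2 ran from 0 (BPH_vehicle replicate 6) to 0.950 (BPH_Cmpd17b replicate 3) of the count predicted, so the mix of kidney transcripts was not always that of the kidney-like library. For the other markers the share of 83.1% is consistent with RNA or reads from a kidney source, as a hypothesis. Whether it entered at dissection, in library making or in sequencing stays open, as does a biological difference between the groups.

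Among the 1394 genes called between the strains under vehicle that could be placed, 33.9% had a called neighbour in gene order, where 1000 shuffles gave a median of 17.6%, a central 95% range that ended at 20.4% and a maximum of 22.4%. Inherited chromosome segments that differ between the strains may account for part of the calls, but this share of 33.9% shows only that called genes lie together. Near-identical copies were not taken out before the shuffles. Copies that lie side by side can also raise the share, so it cannot tell segments from copies. The tables argue against reads shared between near-identical copies as the whole cause: predicted genes, pseudogenes and clone-named genes made up 21.3% of the called genes (95% interval 19.3 to 23.5%) and 15.0% of the 2936 called with 25 libraries (13.7 to 16.3%), and 1174 of the 1492 were other genes. The bound for this, under 50% in both sets of libraries and under 20% in at least 1, was set after both shares were seen; under an earlier bound of 20% with 26 libraries alone, the test left the question undecided. As part of the cause they stay open, since such genes made up 11.5% of those tested and 49.5% of the 216 called with more than an 8-fold difference, and copies with ordinary names were not counted. Strain variants against the reference stay open too, since 50.2% of the calls were lower in BPH/2J and both strains can carry variants. The difference in blood pressure between the strains is confounded with their genomes and stays open as untested.

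Among other splits of the samples, 1 of 80, the real one, gave as many called genes between the strains under vehicle (1492, highest other 1; with 25 libraries 2936, highest other 1775) and under Cmpd17b (1195, highest other 0; with 25 libraries 2197, highest other 0), so chance can be excluded for them. In the split with 1775 calls only 2 of the 14 libraries had changed sides, so it stayed close to the strain grouping. For Cmpd17b, counts at an unadjusted p under 0.05 were reached by 32 of 80 splits in BPH/2J (970, highest other 2626), 24 in BPN/3J (683, 1946), 64 for the interaction (341, 2449) and 10 for the average (1319, 2347). With 25 libraries they were reached by 54 (287, 1435), 20 (1506, 3472), 45 (595, 2612) and 18 (1017, 3464) of 80. Chance cannot be excluded for these. Splits with several times the real count may point to a structure of the samples that the groups leave out, which was not tested, and correlated genes alone can raise the highest count.

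Single libraries stood apart in many genes named here: 67 of 316 tests of a sample's gap to its group passed, where chance gives about 1 in 20, or 15.8, for normally distributed values. The CPM tested were not logged or adjusted for batch, and some genes lay near 0, so 15.8 is not a firm expectation. BPH_Cmpd17b replicate 6 was the only batch 2 library of its group in the tests of genes. The gap divided by the range of the group follows each gene. BPN_vehicle replicate 7 was high in Myh7 (0.593), Col1a1 (0.744), Serpina3h (0.757), Rps15a-ps5 (0.629), Sycp2 (0.732), H2-K1 (0.668, at 248 CPM), H2-Q4 (0.729), Mmp3 (0.810), Mertk (0.642), Kcnab1 (0.680), Xaf1 (0.592), Tap1 (0.660), Gbp3 (0.691), Angpt2 (0.765), Pih1d1 (0.636), Gamt (0.601), Fabp4 (0.802), Emcn (0.777) and Bst2 (0.586), and low in Angpt1 (0.632) and Il15 (0.690). BPH_Cmpd17b replicate 6 was high in Nppa (0.870), Nppb (0.785, at 390 CPM), Col1a1 (0.923), Col3a1 (0.908), Mfap4 (0.890), Col6a3 (0.752), Nmrk2 (0.774), Acta1 (0.816), Cthrc1 (0.952), Lox (0.979), Rps21 (0.686) and Ankrd1 (0.748), and low in Emcn (0.645). BPH_Cmpd17b replicate 4 was high in Edn3 (0.679), H2-K1 (0.804), H2-Q4 (0.650), H2-Q6 (0.645), Tap1 (0.701) and Gbp3 (0.748).

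Other libraries stood apart in 1 to 3 genes each. BPN_vehicle replicate 1 did in Tafa2 (0.688) and Gzma (0.726), replicate 2 in Zfp33b (0.607) and replicate 4 in Ren1 (0.603) and Ncr1 (0.744). BPN_Cmpd17b replicate 1 stood apart in Eno1b (0.888) and Lox (0.770), replicate 2 in Myh7 (0.918), Ren1 (1) and Plppr1 (0.741), replicate 3 in Rps21 (0.843), and replicate 5 in Nppa (0.833), Cubn (0.776) and Cyp2b10 (0.744). BPH_vehicle replicate 3 stood apart in Fpr1 (0.780) and Serpina3k (0.722), replicate 4 in Kcne1 (0.599), and replicate 7 in Nmrk2 (0.752), Cthrc1 (0.668) and Rps21 (0.644). BPH_Cmpd17b replicate 2 did in Serpina3h (0.644) and Cyp2b10 (0.794), and replicate 5 in Fpr1 (0.636), Ren1 (0.670) and Serpina3k (0.782).

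For 10 lists, 8 with 26 libraries and 4 with 25, 2 of them in both, the Cmpd17b effect differed between the strains by camera with the preset correlation. With 26 libraries the medians of the interaction were -0.16 for sarcomere, -0.28 for calcium handling, -0.24 for cardiac ion channels, -0.21 for sympathetic and adrenergic signalling, -0.25 for fatty acid oxidation, -0.10 for the respiratory chain, 0.47 for erythroid and -1.05 for skeletal muscle genes. Of these 8 calls, 6 ended without the kidney-like library: sarcomere (0.0189, adjusted p = 0.94), calcium handling (-0.12, adjusted p = 0.0505), ion channels (-0.10, adjusted p = 0.0505), sympathetic (-0.16, adjusted p = 0.0587), respiratory chain (-0.00155, adjusted p = 0.624) and skeletal muscle (-0.88, adjusted p = 0.167). All 6 also ended without 1 of several other libraries: sarcomere, calcium handling, ion channels and sympathetic without BPH_vehicle replicate 1 (-0.09, -0.21, -0.15 and -0.19) or 7 (-0.09, -0.20, -0.18 and -0.18), skeletal muscle without BPH_vehicle replicate 1 (-0.99), the respiratory chain without BPH_vehicle replicate 7 (0.00372) or BPN_vehicle replicate 4 (-0.06), and sympathetic without BPN_Cmpd17b replicate 2 (-0.19) or BPN_vehicle replicate 3 (-0.17) or 7 (-0.11). Skeletal muscle moved to -0.69 without BPH_vehicle replicate 4 and erythroid to 0.27 without BPN_vehicle replicate 7, both still called. Without the batch term the erythroid call ended (0.33, adjusted p = 0.0823). With 25 libraries they were 0.28 for cardiac stress (adjusted p = 0.000383), -0.18 for fatty acid oxidation (adjusted p = 2.2e-08), 0.30 for endothelial (adjusted p = 0.0158) and 0.49 for erythroid genes (adjusted p = 0.00467). Without BPN_vehicle replicate 7 the endothelial (0.0338, adjusted p = 0.667) and erythroid calls (0.31, adjusted p = 0.105) ended, as did the erythroid call without BPN_Cmpd17b replicate 3 (0.38, adjusted p = 0.063) and the endothelial call without the batch term (0.24, adjusted p = 0.0852). Without BPH_Cmpd17b replicate 6 the cardiac stress median was 0.14 (adjusted p = 0.0233). None held with an estimated correlation, where the smallest adjusted p was 0.884 with 26 libraries and 0.826 with 25.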

How the results depend on the processing

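The sets of 25 and of 23 libraries were chosen only after the data were seen, and so were all fits within the 25; the other alternatives were planned. No paired analysis was possible because replicate numbers follow the order of the samples and link no animals. Of the alternatives for log2 differences of named genes, 4956 kept their direction and their side of the threshold, 102 lost the call, 54 gained it, and 112 changed sign with no call before or after. No called value changed sign. Of those for gene lists 1465 kept camera's direction and the call, 220 lost the call and 35 reversed camera's direction. The drug contrasts gave 0 calls in all alternatives except those named next. The cause of the changes below was not tested. At this depth, genes such as Fpr1, Fpr2 and Ren1 lay under the filter.

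Counts moved by over 1.5 times as follows. The strain difference under vehicle, 1492 genes, was 2402 in batch 1 alone, 4009 with voom and 3976 with 23 libraries, and 1291 to 1718 on leaving out 1 library. With 25 libraries, 2936, it was 1168 in batch 2 alone (fewer libraries) and 2598 to 3751. Under Cmpd17b, 1195, it was 1961 in batch 1 alone, 3339 with voom, 1793 without a batch term (1182 higher), 779 with only the 2 groups, 2942 with 23 libraries, and 936 to 2197, the latter without the library labelled BPH_Cmpd17b replicate 7. With 25, 2197, it was 3405 with voom and 1834 to 2066. With 25 libraries Cmpd17b in BPH/2J gave 249 calls in batch 2 alone, and Cmpd17b in BPN/3J gave 1 with DESeq2. Calls of gene lists over the 6 contrasts, 51 with 26 libraries, were 0 with an estimated correlation, 5 with fry and 34 to 80 on leaving out 1 library (80 without BPH_Cmpd17b replicate 6). With 25 libraries, 34, they were 0, 12 and 30 to 51. The opposition of the drug effect to the strain difference, judged against the SD of the simulated covariances, moved from -0.0369 to -0.0174 with divided controls, -0.00739 for genes at an average log2 CPM of at least 1 and -0.0159 in batch 1 alone, and with 25 libraries from -0.00949 to -0.00106 for such genes and, reversed, to 0.0104 with divided controls.

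The lists whose direction by camera reversed are given with their medians, which changed sign too unless noted. For Cmpd17b in BPH/2J, in batch 1 alone and with 23 libraries, they were calcium handling (0.0408, 0.0315), ion channels (0.0533, 0.0449), glycolysis (0.0425, 0.0446), heat shock (-0.000634, sign kept, and 0.000895), sarcomere (0.0501, 0.0432) and ventricular cardiomyocyte (0.0374, 0.0303). In batch 1 alone endothelial (0.00372), nitric oxide and angiogenic (-0.00875, sign kept) and sympathetic genes (0.00278) also reversed. For the average it was fatty acid oxidation (0.0414, 0.00896), sarcomere (0.0344, and -0.00385, sign kept), nitric oxide with 23 libraries (0.00586) and ventricular cardiomyocyte in batch 1 alone (-0.00236, sign kept). For the interaction it was the respiratory chain (0.0104, 0.00855) and sarcomere (0.0412, 0.0794), and in BPN/3J nitric oxide with 23 libraries (-0.000192, sign kept). On leaving out 1 library the medians in BPH/2J ran from -0.31 to -0.00365 for ion channels (sign kept), -0.16 to 0.00875 for glycolysis, -0.10 to 0.0148 for heat shock and -0.34 to 0.0269 for sarcomere, and the average from -0.22 to 0.0231 for sarcomere. The library labelled BPH_Cmpd17b replicate 7 gave each of these reversals. With 25 libraries they ran from -0.0124 to 0.21 for cardiac stress and -0.16 to 0.31 for extracellular matrix in BPH/2J, both reversed without BPH_Cmpd17b replicate 6, and for the interferon response from -0.29 to 0.00495 in BPN/3J and -0.15 to 0.0140 on average, both reversed without BPN_vehicle replicate 7. Other medians changed sign while camera's direction stayed: without the library labelled BPH_Cmpd17b replicate 7, calcium handling (0.00586), fibroblast (0.0383), interferon response (0.00350) and sympathetic genes (0.00426) in BPH/2J and sarcomere for the interaction (0.0189); without BPH_vehicle replicate 7, the respiratory chain for the interaction (0.00372); in BPH/2J, interferon response in batch 1 alone (0.0196) and endothelial with 23 libraries (0.00167).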

Other observations

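The comparison of Cmpd17b with vehicle without the 3 libraries that stand apart, and the values from single libraries, were chosen only after the data were seen.

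Cell type markers and metabolic genes held further differences between the strains. With 25 libraries and vehicle, 12 of 41 genes of oxidative stress and NRF2 targets were lower in BPH/2J and 1 higher (12 and 2 when adjusted over the list alone), with a median of -0.12 and a camera adjusted p of 0.327. Of 42 fatty acid oxidation and lipid handling genes 10 were lower and 2 higher (11 and 2 when adjusted over the list alone), with a median of -0.07. Of 10 pericyte markers 3 were lower and 0 higher (6 and 0 when adjusted over the list alone), with a median of -0.29 (fry 0.0257, camera 0.253). Of 28 heat shock genes 6 were lower and 0 higher, also when adjusted over the list alone. This heat shock share is near the 18.9% called among all genes tested with 25 libraries. On Cmpd17b 4 Schwann cell and neuron markers were higher and 0 lower (fry 0.0195).

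The medians of 12 fibroblast markers for Cmpd17b in BPH/2J followed the libraries used. With 26 libraries the median was -0.16 (camera adjusted p = 0.00253, and adjusted p = 0.521 with an estimated correlation), and without the library labelled BPH_Cmpd17b replicate 7 it was 0.04 (camera adjusted p = 0.71). Without the 3 libraries that stand apart it was -0.17, 0 of 12 positive (camera adjusted p = 1.8e-07, and adjusted p = 0.18 with an estimated correlation), and in batch 1 alone -0.15, again 0 of 12 positive (camera adjusted p = 9.6e-06, and adjusted p = 0.51 with an estimated correlation). Both of these fits leave out BPH_Cmpd17b replicate 6, a Cmpd17b library far above its group in Col1a1 (305 CPM), Col3a1 (746 CPM) and Mfap4 (55.6 CPM), so they are not a test of a drug effect on fibroblasts. The extracellular matrix list had a median of -0.14, 7 of 59 positive, without the 3 libraries (camera adjusted p = 1.8e-07, and adjusted p = 0.465 with an estimated correlation). In BPN/3J the fibroblast median without them was 0.06 (adjusted p = 0.618). The interaction was -0.21 without them, 0 of 12 positive (camera adjusted p = 0.000688, and adjusted p = 0.777 with an estimated correlation), and -0.04 in batch 1 alone (adjusted p = 0.484). In BPH/2J no gene was called by edgeR without the 3 libraries, where 410 had an unadjusted p under 0.05.

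Transcripts of other tissues appeared in some libraries. Myl7, an atrial light chain, stood at 72.8 CPM in BPH_vehicle replicate 7 and at most at 1.43 CPM in the other libraries. Sftpc, a surfactant protein of the lung, stood at 6.84, 1.41 and 1.60 CPM in BPN_vehicle replicates 1 and 2 and BPH_vehicle replicate 7. Alb, of the liver, stood at 212, 337 and 35.3 CPM in BPN_vehicle replicates 1, 2 and 4. BPN_vehicle replicates 1 and 2 and BPH_vehicle replicate 7 were in batch 2, as was the kidney-like library, and BPN_vehicle replicate 4 was in batch 1. Sftpc was at most 0.113 CPM in batch 1 libraries and 0 in the other batch 2 libraries. A link to batch was not tested.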
